A study of Solanum lycopersicum with 9 samples.

How the data were processed

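The series measured gene expression in red ripe tomato fruit (Solanum lycopersicum, cv Money Maker) on 9 single-sample Affymetrix tomato arrays. Per the labels' protocols, RNA was extracted from pools of fruit mesocarp with TRIzol, its integrity was read on a Bioanalyzer, and biotin-labelled cRNA was made with a MessageAmp kit. The labels placed 3 pools in wild type (WT), 3 in the antisense line AS5 and 3 in the antisense line AS17.

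The deposited values were log2 expression values, 1 per probe set and array, and the submitters' processing notes named RMA, a method that corrects background, normalises arrays to each other and summarises probes on the log2 scale. Its version, settings and probe definitions were not given in the sources used here. The deposited values ran from 0.26 to 12.9 and carried no detection calls, and they were used without further scaling. Array medians over the tested probe sets lay between 5.24 and 5.47. The highest was that of AS5 pool 3, and the next highest, in WT pool 2, was 5.33.

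The table held 10209 probe sets. The 171 Affymetrix control probe sets were left out of the tests and examined separately, which left 10038. Genes were named through the platform annotation, which is old: 909 probe sets had 1 gene symbol, 0 had several, and 9129 had none in the table used and are called unnamed here. The 909 named probe sets stood for 802 genes. Of them, 885 matched the RefSeq gene table of tomato assembly SLM_r2.1 by Entrez identifier, which was used for synonyms only. The build behind the array design was not given in the sources used here, so no coordinates are given. For a gene with more than 1 probe set, the 1 with the highest mean over all arrays represented it.

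A background level was set per array as the 95th percentile of the 63 control probe sets for reporter genes. Whether any of these probe sets responds to sequence of the antisense construct was not tested. The level lay between 1.41 and 1.56 in WT arrays and between 1.57 and 1.98 in silenced-line arrays, so it is confounded with the silencing. An equal value is thus more readily at background in a silenced-line array, which favours counting losses over gains. Where every array of a group was at or below it, the fold is written as a lower bound. That bound is the mean of the brighter group minus the dimmer group's mean of the higher of background and measured value, all on the log2 scale.

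Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group over all 9 arrays. Contrasts were AS5 minus WT, AS17 minus WT, the mean of both lines minus WT, and AS17 minus AS5. Probe sets passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Errors of changes are limma's standard errors (SE), and errors of levels are standard deviations (SD) over pools. All adjusted p-values of single genes come from this fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene, the 802 named genes as background, at least 3 genes per list and Benjamini-Hochberg adjustment over the lists of a contrast. Estimated correlations and fry, a self-contained test, were alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

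The groups, contrasts, thresholds, 20 gene lists, naming rule and most alternatives were chosen before the data were examined. List members were matched by whole symbol or synonym, since the annotation used gave no product names. A synonym did not count if it was another gene's symbol or if the gene's own symbol stood in another list. This left 14 lists with at least 3 genes. Of the other 6, the lists for the ASR family, seed and embryo markers, vascular markers and ribosomal proteins had 0 named genes, water channels had 1 and heat shock genes had 2. A further 14 lists were built from the annotation's symbols after the data were seen. The naming rule took, per contrast, up to 12 named genes that rose and 12 that fell with adjusted p under 0.05 and no overlap between the groups' arrays. It added up to 4 members per list with the smallest p for the mean of both lines, up to 2 unnamed probe sets per direction, and the 10 smallest p where under 10 probe sets passed.

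Alternatives covered filters on dim probe sets, median centring, quantile normalisation, variance trends, robust variances, array weights, pool number as a block, other thresholds, 1 probe set per gene, 2-group fits and leaving out each array. Leaving out AS5 pool 3 and AS17 pool 1 together, camera with all probe sets as background, lists without genes at background on all arrays, and the 14 further lists were added after seeing the data. Levels of Asr1, planned as a check of the silencing, were not analysed here because no probe set carried that name.

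The code was tested on simulated data with the arrays' own means and variances, with sets of probe sets changed equally in both lines. For the mean of both lines minus WT it called 95.5% of changes of 2 log2 units, 71.6% of changes of 1 and 25.4% of changes of 0.5, with 5 unchanged probe sets called. For AS5 minus WT the shares were 90.9%, 55.2% and 13.4%, and for AS17 minus WT 92.4%, 64.2% and 14.9%. Camera called 0 of 14 unchanged lists in each contrast. The simulated noise was independent between genes, so this does not show how camera behaves when genes of a list vary together. The number of arrays limits the precision of every value.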

Results

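Asr1 encodes a small protein that takes its name from abscisic acid, stress and ripening. The series compared ripe fruit of plants in which an antisense construct silenced this gene with fruit of wild-type (WT) plants. Mesocarp of red ripe fruit was profiled in 3 pools of WT, 3 of line AS5 and 3 of line AS17. The labels describe pools from different plants of each line, so n counts pools, and the silencing itself is represented by 2 lines. Expression is given as deposited log2 values of 10038 probe sets, of which 909 (9.06%) carried a gene symbol. Between 19.6% and 25.8% of the probe sets of an array were at or below the background level.

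No probe set was named Asr1 or another member of the ASR family, so the level of the silenced gene was not analysed here and the silencing was not checked on these arrays. Groups below are those of the labels. Correlations between arrays, computed across probe sets and so not over independent replicates, lay between 0.976 and 0.996. The first principal component held 40.1% of the variance. AS5 pool 3 and AS17 pool 1 scored 33.4 and 35.0 on it, and the other arrays from -27.2 to 12.5. On the second component, with 21.9%, the 3 WT arrays scored 11.3 to 19.5, AS5 pools 1 and 2 scored -12.1 and -8.48, and AS17 pools 2 and 3 scored -22.5 and -22.0. AS5 pool 3 and AS17 pool 1 scored 16.3 and 6.64 on it, on the side of the WT arrays. In a sign of RNA quality, the 3′ minus 5′ signal of control genes, these 2 arrays were below the other 7 for gapdh (0.619 and 0.550) and ubiquitin (1.12 and 1.36).

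**Figure D1:**
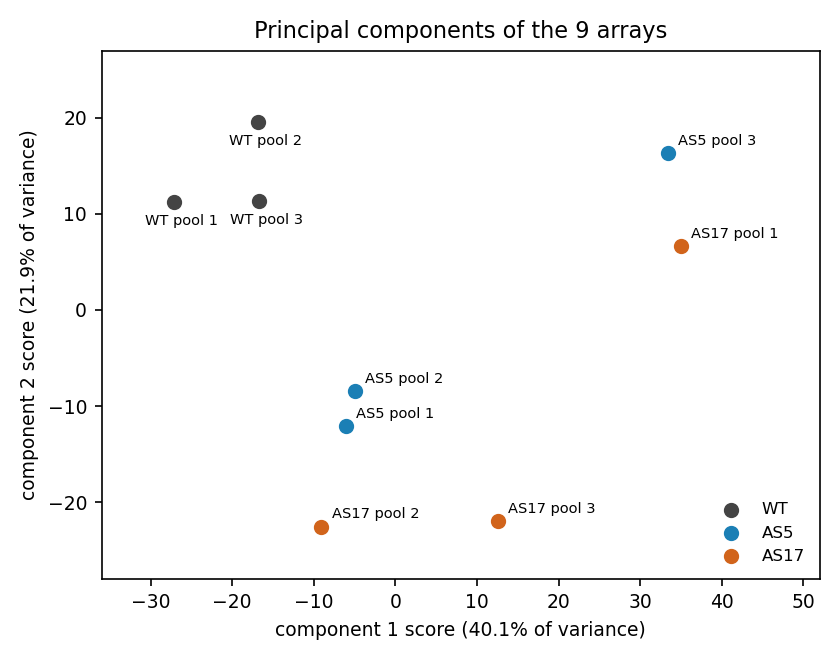
Scores of the 9 arrays on the first 2 principal components of the deposited log2 values (40.1% and 21.9% of the variance), coloured by group. AS5 pool 3 and AS17 pool 1 lie at 33.4 and 35.0 on component 1, apart from the other pools of their lines.

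The mean of both silenced lines was compared with WT to find transcripts that differed in silenced fruit. LOC543645 stood at 7.19 ± 0.62 (SD, n = 3) in WT and at background in all 6 silenced pools, at least 44.5-fold lower (adjusted p = 1.7e-06). SNF4, a regulatory subunit of the SnRK1 energy-sensing kinase, stood at 3.94 ± 0.23 (SD, n = 3) in WT and at background in 4 of 6 silenced pools, at least 4.05-fold lower (adjusted p = 0.000552). Of those values, 1.77 in AS5 pool 1 and 1.85 and 1.63 in AS17 pools 2 and 3 were above the highest WT background level, 1.56. NP24-I, an osmotin-type defence protein, fell by 1.64 (SE 0.14, adjusted p = 0.000817) from 11.9 ± 0.15 in WT. ER1 fell by 3.43 (SE 0.53, adjusted p = 0.0221) and P18, a dUTPase, by 1.93 (SE 0.28, adjusted p = 0.0173). FPPS1, which makes farnesyl diphosphate for sterols and sesquiterpenes, fell by 1.52 (SE 0.24, adjusted p = 0.0248).

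Smaller falls were measured for copz1, a coatomer subunit (-0.88), CAT2, a catalase (-0.84), and MFP1, a filament-like protein that binds chromatin attachment regions (-0.83). FLACCA, the molybdenum cofactor sulfurase needed for the last step of abscisic acid synthesis, changed by -0.83, the gibberellin oxidase gene GA3ox1 by -0.80, and the phytoene synthase gene PSY2 by -0.61 (adjusted p from 0.0253 to 0.0471 for these 6 genes). LOC543515, whose synonym is LEXYL2, a xylosidase of the cell wall, rose by 0.90 (SE 0.13, adjusted p = 0.0166), from 3.62 ± 0.04 in WT to 4.46 ± 0.29 in AS5 and 4.58 ± 0.12 in AS17 (n = 3 each). GS2 also passed (adjusted p = 0.0406) with all arrays at or below background, so no fold is given.

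**Figure D2:**
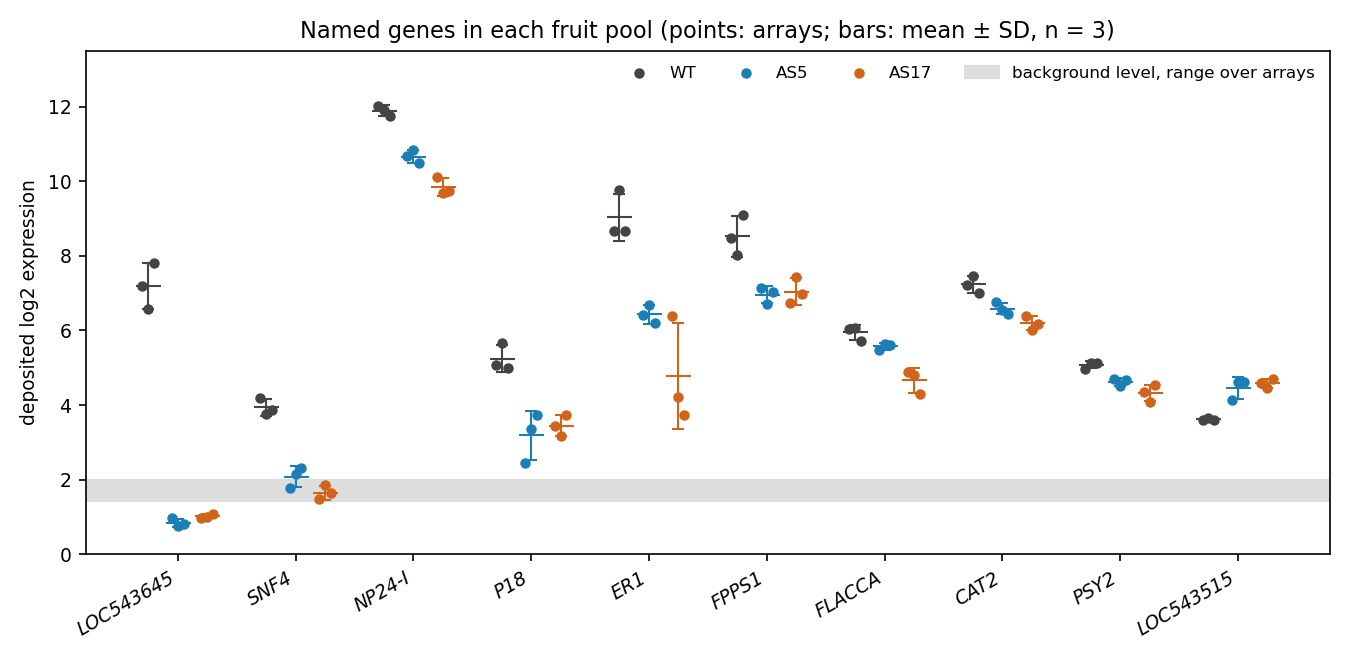
Deposited log2 expression of 10 named genes in each array (points), with the mean and SD of each group (bars, n = 3) and the range of the background level over arrays (grey band). LOC543645 lies near 7.19 in WT and below the band in every silenced pool, and LOC543515 is the one gene plotted that was higher in the silenced lines.

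Across all probe sets, 128 passed for the mean of both lines, 39 higher and 89 lower, and 15 of them carried a gene symbol. Unnamed probe sets held some of the widest differences. One, called here the lost probe set, stood at 5.59 in WT and at background in all silenced pools, at least 14.7-fold lower (adjusted p = 1.59e-07). Another, called the brightest probe set, was at 12.84 ± 0.03 (SD, n = 3) in WT, the highest value of each WT array. Its measured change of -4.15 (SE 0.14, adjusted p = 1.66e-06) is given as a lower bound on its fall for that reason. A probe set at 1.63 ± 0.72 in WT, called the gained probe set, rose (adjusted p = 0.00734) by a measured 3.85, with 1 of 3 WT arrays at background, or 13-fold with values under background raised to it. A further one also rose (adjusted p = 0.0483), by a measured 3.78 with 2 of 3 WT arrays at background, so no exact fold is given. LOC543645, SNF4 and NP24-I passed under every alternative run, at adjusted p up to 0.000134, 0.00569 and 0.0189, while the other named genes passed in 0 to 6 of the 9 fits with 1 array left out. The count was 27, 37 and 51 without WT pools 1, 2 and 3, 62 and 49 without AS5 pools 1 and 2, 70 without AS17 pool 3, and 208 without both AS5 pool 3 and AS17 pool 1.

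In AS5 alone, 38 probe sets differed from WT, 9 higher and 29 lower, and 4 of them carried a gene symbol. LOC543645 was at least 45.5-fold lower (adjusted p = 6.75e-06). P18 fell by 2.06 (SE 0.32, adjusted p = 0.0397), SNF4, at background in 1 of 3 AS5 pools, by 1.86 (SE 0.18, adjusted p = 0.00371) and NP24-I by 1.23 (SE 0.16, adjusted p = 0.0142). Among unnamed probe sets, the gained probe set rose by a measured 3.71, from a WT level near background, and another rose by 2.01 (adjusted p = 0.0259 and 0.0164). The brightest probe set had a measured change of -4.39, with the same limit (adjusted p = 3.55e-06), and the lost probe set was at least 15.0-fold lower (adjusted p = 5.76e-07). LOC543645 and SNF4 passed in all 9 fits with 1 array left out, NP24-I in 6 and P18 in 1. The count was 18 without any 1 WT pool, and 21 and 22 without AS5 pools 1 and 2.

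In AS17, 135 probe sets differed from WT, 29 higher and 106 lower, and 16 of them carried a gene symbol. The 12 named genes with the widest falls began with LOC543645 (at least 43.6-fold lower, adjusted p = 6.51e-06), ER1 (-4.26, adjusted p = 0.0195) and SNF4 (at least 4.58-fold lower, adjusted p = 0.000742). ER1 stood at 6.38, 4.22 and 3.72 in AS17 pools 1, 2 and 3, and its change ran from -5.06 to -3.74 over the alternatives. TomloxE, a lipoxygenase, fell by 2.11 (SE 0.39, adjusted p = 0.0423), NP24-I by 2.04 (SE 0.16, adjusted p = 0.000691), P18 by 1.80 (SE 0.32, adjusted p = 0.0385) and FPPS1 by 1.48 (SE 0.28, adjusted p = 0.0444). FLACCA changed by -1.29, MFP1 by -1.14, copz1 by -1.13, CAT2 by -1.04 and GA3ox1 by -0.88 (adjusted p from 0.0153 to 0.0493). LOC543515 rose by 0.96 (SE 0.15, adjusted p = 0.0281). PSY2 also fell, by 0.76 (adjusted p = 0.036). The gained probe set rose by a measured 3.99, from a WT level near background, and another unnamed one by 3.42 (adjusted p = 0.0137 and 0.0442). That other one was at 4.86, 7.41 and 6.14 in WT pools 1, 2 and 3, and its change ran from 2.79 to 4.06 over the alternatives. The lost probe set was at least 14.4-fold lower and the brightest probe set had a measured change of -3.90, with the same limit.

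With 1 array left out, LOC543645, SNF4 and NP24-I passed in all 9 fits, FLACCA in 7, and the other genes given above for AS17 in 1 to 5. The AS17 count was 22, 35 and 35 without WT pools 1, 2 and 3, 73 and 48 without AS5 pools 1 and 2, 20 without AS17 pool 3, and 315 without both AS5 pool 3 and AS17 pool 1. Median centring gave 37 higher and 77 lower, and quantile normalisation 41 higher and 88 lower.

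Genes that changed in both lines address what the 2 lines share. Calls in the same direction numbered 35, of which 8 were higher and 27 lower, and LOC543645, SNF4, NP24-I and P18 were the named genes among them. AS17 had 100 calls that AS5 lacked, and 99 of these had the same sign in AS5, where they did not pass. Both contrasts subtract the same WT arrays, which favours equal signs, and no value for unchanged lines was computed for this count. The log2 changes of the lines correlated across probe sets with r = 0.83 (Spearman's rho = 0.74) and a covariance of 0.127. Unchanged groups simulated against shared WT arrays gave a mean r of 0.45, a covariance of 0.0368 and 0 shared calls in 100 draws. The observed covariance lay within the simulated range of -0.0327 to 0.343, and was 0.0902 above the simulated mean. The observed r and rho also lay within their simulated ranges, -0.667 to 0.988 and -0.575 to 0.984. Independent lists of these sizes would share 0.332 probe sets. The 3 WT arrays were not split into separate controls for the 2 lines, so part of the excess may come from the shared WT arrays. The number of shared calls was 15, 14 and 16 without WT pools 1, 2 and 3, 20 and 17 without AS5 pools 1 and 2, and 16 without AS17 pool 3.

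**Figure D3:**
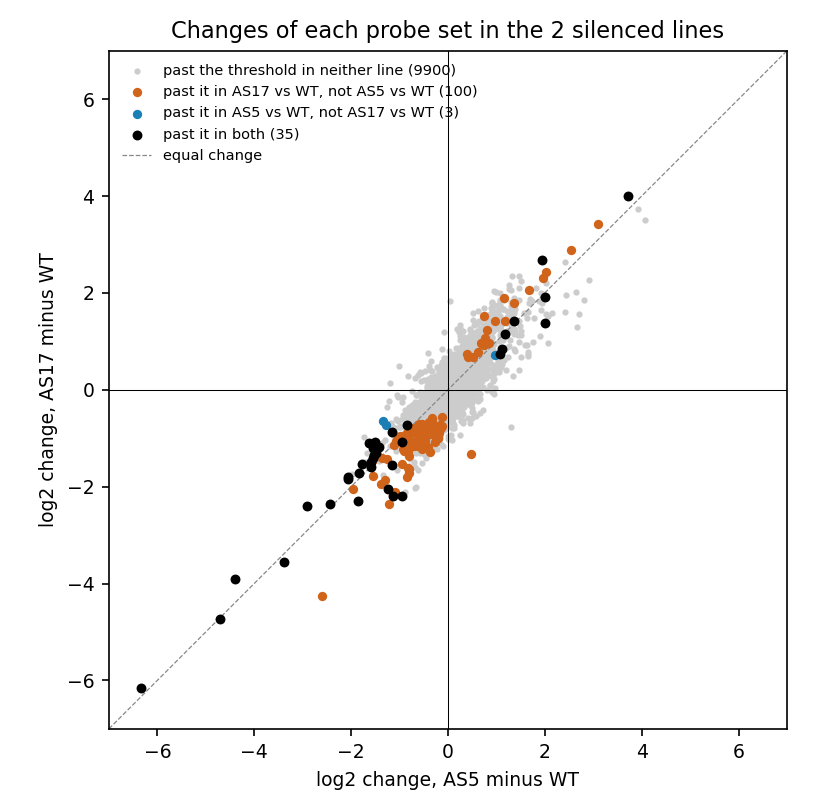
Log2 change of each of 10038 probe sets in AS5 minus WT (x axis) and AS17 minus WT (y axis), coloured by the contrasts in which adjusted p was under 0.05, with the line of equal change dashed. The 35 probe sets that passed in both lines lie in the quadrants of equal sign.

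Gene lists were examined for the mean of both lines. In carotenoid and isoprenoid synthesis, 2 of 14 genes fell (FPPS1 and PSY2) and 12 did not pass. Adjusted over the list alone, 3 fell, with PDS, the phytoene desaturase gene, at -0.60 (SE 0.18). The most abundant Psy1 probe set, for the fruit phytoene synthase, was at 12.12 ± 0.02 in WT and had a change of -0.09 (SE 0.09, adjusted p = 0.69) that did not pass. Of the other 2 Psy1 probe sets, 1 had a change of -0.11 that did not pass, and 1, singled out after its values were seen, rose by a measured 3.82 (adjusted p = 0.0421) with 2 of 3 WT arrays at background. The list was lower in AS5 (camera adjusted p = 0.0483, median change -0.08), with an adjusted p = 0.261 with an estimated correlation and 0.0958 in fry. It did not pass without WT pools 1, 2 or 3 (0.0669, 0.0531 and 0.0783), AS5 pool 3 (0.193), or AS17 pools 1 or 3 (0.0508 and 0.053). For the mean of both lines it did not pass in camera (adjusted p = 0.14, or 0.337 with an estimated correlation), and passed in fry (0.0389).

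In cell wall modification, 1 of 27 genes rose (LOC543515). Adjusted over the list alone, 2 rose and 2 fell: the expansin gene EXPA4 at 1.91 (SE 0.41) beside LOC543515, and the galactosidase genes TBG2 and TBG5 at -0.67 (SE 0.16) and -0.51 (SE 0.10). Of 6 abscisic acid genes, 1 fell (FLACCA). Adjusted over the list alone, the same 1 fell and 2 rose: NCED1, for the epoxycarotenoid cleavage step of abscisic acid synthesis, at 0.82 (SE 0.18), and the dehydrin TAS14 at 1.04 (SE 0.33). Of 21 pathogenesis-related and wound genes, 1 fell (NP24-I). Adjusted over the list alone, 1 fell and 1 rose, the wound-inducible aminopeptidase LAPA1 at 1.78 (SE 0.46). Of 9 redox genes, 1 fell (CAT2), and adjusted over the list alone also 1.

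In amino acid and GABA metabolism, 0 of 12 genes passed over all probe sets. As a list it did not pass in camera (adjusted p = 0.14, or 0.337 with an estimated correlation), and passed in fry (0.00437). Adjusted over the list alone, 2 rose: gad2 at 1.78 (SE 0.41) and GABA-TP2 at 1.57 (SE 0.42). Their synonyms include GAME11 and GAME12, names of genes of steroidal glycoalkaloid synthesis. Symbols were matched without regard to case, so gad2 may not be the glutamate decarboxylase gene that the list was meant to hold. The rises of gad2 and GABA-TP2, and the list's result in fry, therefore do not show that GABA metabolism rose. None of 29 ethylene genes passed, and adjusted over the list alone 1 rose, ACO6, an ethylene-forming oxidase, at 1.36 (SE 0.30). None of 10 cell cycle genes passed, and adjusted over the list alone CDKA1 rose (1.14, SE 0.24) and PCNA fell (-0.57, SE 0.15). None of 6 phenylpropanoid genes passed, and adjusted over the list alone 1 rose (hqt, at 0.60, SE 0.17). In the lists for sucrose and hexose metabolism (19 genes), starch (3), ripening transcription factors (7), photosynthesis (3) and epidermis (3), 0 genes passed in either count. RIN and NOR, regulators of ripening, did not pass, at -0.02 and -0.09 (adjusted p = 0.964 and 0.873). The 2 heat shock genes and the 1 water channel gene did not pass.

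Camera called 0 of the 14 lists for the mean of both lines, where the smallest adjusted p was 0.14, and 0 in AS17 against WT, where it was 0.287. It called 1 list in AS5 and 2 between the lines. None of these held with an estimated correlation. For the mean of both lines, the starch, abscisic acid, ethylene and redox lists had medians, means and camera directions of unlike sign. AS5 pool 3 and AS17 pool 1 stood apart in single genes of several lists. In those 2 arrays, PTI5, an ethylene-response type transcription factor, was at 5.34 and 5.56, against 1.37 to 2.16 in the other 7, and ACO5 at 10.5 and 10.6, against 6.08 to 8.83. These genes were chosen after their values were seen.

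**Figure D4:**
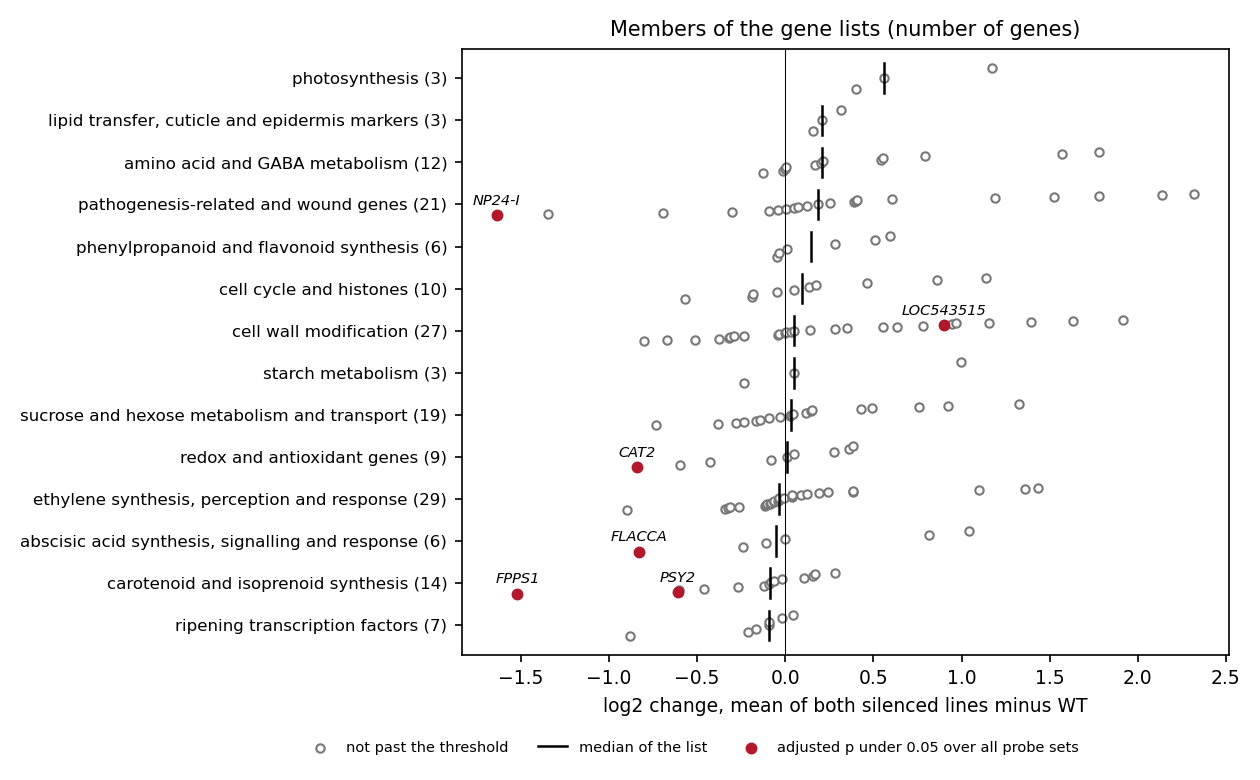
Log2 change of each listed gene for the mean of both silenced lines minus WT (x axis), grouped by list with its number of genes, filled where adjusted p was under 0.05 over all probe sets, with each list's median as a bar. The filled points are FPPS1, PSY2, FLACCA, CAT2 and NP24-I, which fell, and LOC543515, which rose.

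AS17 was compared with AS5 to test whether the lines differed from each other. In limma, 0 probe sets passed, and 591 had an unadjusted p under 0.05. The smallest p belonged to an unnamed probe set at 7.83 ± 0.12 in AS5 and 6.58 ± 0.16 in AS17 (n = 3 each), a difference of -1.25 (SE 0.14) that did not pass (adjusted p = 0.0936). AREB1, a transcription factor of abscisic acid responses, stood at 4.64 ± 0.06 in AS5 and 3.86 ± 0.20 in AS17 (n = 3 each, adjusted p = 0.478). NP24-I and FLACCA, at -0.81 and -0.91, did not pass either (adjusted p = 0.585 for both). As a list, abscisic acid genes were lower in AS17 (camera adjusted p = 0.0288, median difference -0.40), with an adjusted p = 0.264 with an estimated correlation. Adjusted over the list alone, 3 of its 6 genes fell (AREB1, FLACCA and ZEP). Cell wall genes were higher in AS17 as a list (camera adjusted p = 0.0396, median difference 0.07), with an adjusted p = 0.264 with an estimated correlation, and adjusted over the list alone 0 of its 27 genes passed. Neither list passed without AS5 pool 1 (adjusted p = 0.084 and 0.19) or without AS17 pool 1 (adjusted p = 0.0534 and 0.102), and the cell wall list also did not pass without AS5 pool 3 (0.0871) or AS17 pool 3 (0.0859).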

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

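The tests on AS5 pool 3 and AS17 pool 1, the test without genes at background on all arrays, and the lists for heat shock proteins, expansins and phospholipase D with the count of other splits for them, were chosen after the result was seen.

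AS5 pool 3 and AS17 pool 1 lay apart from the other 4 silenced pools, at 33.4 and 35.0 on the first principal component. AS5 pool 3 also had the highest median of all arrays (5.47), while AS17 pool 1 did not stand out in it (5.26). The 3′ minus 5′ signal of 4 control genes exceeded the other 7 arrays in 0 genes for either array, which argues against greater RNA degradation, but both were below the other 7 in gapdh (0.619 and 0.550) and ubiquitin (1.12 and 1.36). Hybridisation spike-in signals (8.38 and 8.45) put both arrays, 2 of 2, within the range of the others, which argues against a weaker hybridisation. LOC543645 was at background in both, with a measured value 5.59 log2 units under the lowest WT array for the nearer one. That gene was picked for having no overlap between silenced and WT arrays as labelled. Its level therefore cannot decide whether an array was exchanged with a WT array. Over all probe sets, these 2 arrays correlated with the WT arrays at 0.976 to 0.983, and the WT arrays with each other at 0.992 to 0.996. Those values argue against such an exchange, although both arrays lay on the WT side of the second component. A difference in RNA quality other than greater degradation, or one in fruit stage or handling, may remain, and no biological explanation was tested.

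Among 171 Affymetrix control probe sets outside the main tests, 5 had all 6 silenced arrays above all 3 WT arrays, where chance gives 2.04. In the main tests, 9.06% of probe sets had no overlap between silenced and WT arrays in either direction, where chance gives 2.38%. The count of 5 controls covers only the higher direction, so it cannot be set against that share, and no excess over the other probe sets is claimed. Of these 5, 3 measure ubiquitin, and controls with all silenced arrays below WT were not counted. AFFX-Le_Ubiquitin_3_at was higher in the silenced lines by 0.87, AFFX-Le_Ubiquitin_5_at by 1.02, AFFX-Le_Ubiquitin_M_at by 0.97, AFFX-Les-actin-M_at by 0.36 and AFFX-Le_GlutTrans_M_r_at by 0.26 (log2), and none passed (adjusted p = 0.4 to 0.531). For the 3′ ubiquitin probe set a 2-sided exact permutation test gave p = 0.0119, and 0.0833 after Benjamini-Hochberg adjustment over 7 measures. That p is the smallest that 84 splits allow. This probe set is among the 5 already without overlap between the groups, so the test adds no support.

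Lists differed between the lines. Abscisic acid genes were lower in AS17 than in AS5 (camera adjusted p = 0.0288), cell wall genes higher (0.0396), heat shock proteins lower (0.000344), expansins higher (0.000344) and phospholipase D genes lower (0.049). With an estimated correlation these became adjusted p = 0.264 for the first pair and 0.367 for the others. All 8 heat shock genes had negative differences (median -0.58), and 0 passed over all probe sets or adjusted over the list alone. Of 12 expansin genes, 4 were at background on all arrays, and 7 of the other 8 had positive differences (median 0.52). Over all probe sets 0 passed, and adjusted over the list alone 1 did (EXPA6). Heat shock and expansin lists passed with any 1 array left out, but not in fry (adjusted p = 0.249 and 0.304), nor did phospholipase D (0.249). Without genes at background on all arrays, expansins passed (0.000142) and phospholipase D did not (0.0667). The phospholipase D list did not pass without WT pools 1 or 3 (0.0595 and 0.0546), AS5 pools 2 or 3 (0.0635 and 0.151), or AS17 pools 2 or 3 (0.182 and 0.218).

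Other splits of the same arrays were counted for each result. For AS5 against WT, 1 of 10 splits, the real one, gave 38 probe sets, and the highest other gave 0. For AS17 against WT, 1 of 10, the real one, gave 135, and the highest other 0. With 10 splits the share cannot go under 0.05. For the mean of both lines in a 2-group fit, 2 of 84 splits gave as many as the real 119, a share under 0.05, and the other gave 731. That split set AS5 pool 3, AS17 pool 1 and AS17 pool 3 against the rest, which points to a structure of the samples that crosses the lines. A grouping that ignores the lines thus gave more calls than the real one, so the share makes chance less likely but does not exclude it. For shared calls, 2 of 100 drawn splits gave as many as the real 35, the highest other being 66. No draw set AS5 pool 3, AS17 pool 1 and AS17 pool 3 in the place of WT, the grouping with 731 calls above. The share therefore does not exclude a chance choice of the WT arrays. The splits giving 66 and 21 kept the 3 WT arrays together and mixed the lines, and every other drawn split gave 0. A mix of the lines thus gave more shared calls than the lines themselves, so the count shows nothing specific to the lines. AS17 against AS5 gave 0 probe sets, so 10 of 10 splits gave as many by construction, which decides nothing, and the highest other gave 403.

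For lists, AS5 against WT called 1, as did 3 of 10 splits, the real one included, with a highest other of 1. AS17 against WT called 0, so 10 of 10 splits gave as many by construction, with a highest other of 2, and among the further lists it called 1, as did 3 of 10, with a highest other of 1. AS17 against AS5 called 2 lists, where 1 of 10 splits, the real one, gave as many and the highest other 1. Among the further lists it called 3, where 1 of 10, the real one, gave as many and the highest other 2. With 10 splits none of these shares can go under 0.05. For the mean of both lines 0 lists were called, 84 of 84 splits gave as many by construction, which decides nothing, and the highest other gave 3.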

How the results depend on the processing

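Leaving out AS5 pool 3 and AS17 pool 1 together, camera with all probe sets as background, and lists without genes at background on all arrays, were chosen after the result was seen. Over 218 values of named probe sets and 4900 alternatives, 4478 kept their side of the threshold and their sign, 280 no longer passed and 91 newly passed, with the same sign. The other 51, from 17 values, changed sign and passed in neither fit, and 0 values that passed in either fit changed sign. The cause of the changes below was not tested, except that stricter or looser thresholds and fewer arrays act by construction.

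Dropping the lower 50% of probe sets by mean gave 17 calls in AS5, 56 in AS17, 15 in both lines, 53 for the mean of both lines and 1 between the lines. Using only the arrays of the groups compared gave 47 in AS17 and 20 in both lines. Array weights gave 200, 311, 119 and 556 for AS5, AS17, both lines and the mean. With pool number as a replicate block, AS17 had 74 calls and the mean of both lines 78. In deviations from the group means, 2 of 9 arrays correlated best with an array of their own number. Correlations between arrays of the same number ran from -0.379 to 0.546. These values do not decide whether pool numbers pair the arrays. Requiring a log2 change of at least 1 gave 83 in AS17 and 70 for the mean. At an adjusted p of 0.01 there were 15 in AS5, 20 in AS17, 12 in both lines and 28 for the mean, and at 0.1 there were 58, 354, 252 and 1 in AS5, AS17, the mean and between the lines. Without both AS5 pool 3 and AS17 pool 1, AS17 had 315 calls, of which 109 were among the 135, and the mean had 208, of which 108 were among the 128. The covariance of line changes was 0.107 in the upper 50% of probe sets.

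Leaving out 1 array at a time gave 18 to 38 calls in AS5, 20 to 140 in AS17, 14 to 31 in both lines, 27 to 110 for the mean and 0 between the lines. List calls ranged from 0 to 2 in AS5 and from 0 to 2 between the lines.

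List calls in AS5 were 0 with an estimated correlation, with all probe sets of the listed genes, and without both AS5 pool 3 and AS17 pool 1, and 2 without the lowest 25% of probe sets and with all probe sets as background. Fry called 1 list in AS5, amino acid and GABA metabolism (adjusted p = 0.00849), and not the carotenoid list (0.0958). The amino acid and GABA list holds gad2, whose place in it is uncertain. In AS17 against WT fry called 4 lists. For the mean of both lines it called 2, carotenoid and isoprenoid synthesis (0.0389) and amino acid and GABA metabolism (0.00437). Between the lines, an estimated correlation and pool number as a replicate block gave 0, and fry, all probe sets of the listed genes, and leaving out both pools gave 1 each. Leaving out genes at background on all arrays changed no count of calls among the lists chosen before the data were examined. Among the further lists, phospholipase D between the lines no longer passed in camera (adjusted p = 0.0667). Alternatives for the Asr1 level were not run, since no probe set carried that name. Signal over background limits the values too, since 19.6% to 25.8% of probe sets per array were at or below background.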

Other observations

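The tests on Psy1 and on lost probe sets, and the further lists, were chosen after the result was seen. Of 14 further lists, 0 passed for the mean of both lines. Expansins, which loosen cell walls, were higher in AS17 against WT (camera adjusted p = 0.0309, 12 genes), with an adjusted p = 0.445 with an estimated correlation and 0.081 in fry. Of them 4 were at background on all arrays, and the median of the other 8 was 0.68, with an adjusted p of 0.0146 without such genes, and adjusted over the list alone 3 rose (EXPA3, EXPA4 and EXPA10, at 1.13, 2.36 and 1.11). The list call was lost without WT pool 1 (0.119), WT pool 2 (0.0547) or AS17 pool 3 (0.176). Of 6 Aux/IAA genes, repressors of auxin responses, 1 was at background on all arrays and the other 5 had positive values for the mean of both lines (median 0.58), and the list did not pass (adjusted p = 0.326). Of 7 amino acid and nitrogen transporters, 2 were at background and the other 5 had positive values (median 0.29, list adjusted p = 0.351). Of 8 heat shock protein genes, 7 had positive values in AS5 and 7 negative ones in AS17, and the list passed in neither (adjusted p = 0.407 and 0.254).

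For the mean of both lines, adjusted over the list alone, loxC and TomloxE fell among 5 lipoxygenases (-1.35 and -1.61). PETE and PSBP fell among 9 photosystem, light-harvesting and related genes (-0.89 and -0.91). ME2 fell among 7 genes of malate metabolism (-0.58) and PLDa1 among 5 phospholipase D genes (-0.52), and eIF-5A1 rose among 5 translation factors (0.39). GA3ox1 fell among 6 gibberellin genes. Cytosolic ribosomal proteins (median 0.10), aquaporins (0.10), metallothioneins (0.02) and 14-3-3 proteins (-0.10) had 0 genes past in either count.

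In AS5 pool 3 and AS17 pool 1, 50 probe sets lay more than 1 log2 unit above all other 7 arrays and 0 as far below, and 11 of them were named. That count used the values as deposited, where AS5 pool 3 had the highest array median (5.47) and AS17 pool 1 was at 5.26. Xegip, an inhibitor of xyloglucan-degrading enzymes, was at 4.58 and 5.76 in these arrays and at 0.91 to 1.59 in the others. TSI-1, a stress-induced gene, was at 5.04 and 3.92, against 0.45 to 1.61. These genes were chosen after their values were seen.

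Of 3 Psy1 probe sets, 1 rose for the mean of both lines (measured change 3.82, adjusted p = 0.0421), from 1.77 in WT, with 2 of 3 arrays at background, to 5.70 in AS5 and 5.50 in AS17. It passed in 1 of 9 fits with 1 array left out. The other 2 did not pass, at -0.09 and -0.11. Its measured change differed from that of the most abundant one by 5.33 standard errors, which decides nothing about whether all 3 measure 1 transcript, since the probe set was picked for that difference and its WT level is near background. PSY2 changed by -0.61, which argues against signal from PSY2, and what this probe set measures stays open.

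In 3 probe sets, LOC543645 and 2 unnamed ones, the signal was more than 2 log2 units over background in all 3 WT arrays and at background in all 6 silenced arrays, and 0 probe sets showed the opposite by that measure. The background level was higher in every silenced array than in every WT array, which favours losses in this count. The highest silenced value among these 3 probe sets, 1.54, was still under the highest WT level, 1.56. A sequence difference between the WT plants and both lines that hits probes at random could give such losses, and it cannot be told apart from lower expression: 3 probe sets are too few for a test, since p = 0.25 is the smallest an exact binomial test of 3 can give.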
